A study of Mus musculus with 12 samples.

How the data were processed

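Colorectal tissue from male C57BL/6 mice was profiled on 1-colour (Cy3) Agilent arrays with 60-base probes at 4 time points of the azoxymethane and dextran sulfate sodium (AOM/DSS) model of colon cancer. There were 3 arrays per time point, 12 in all, at 0, 1, 2 and 10 weeks. Per the labels' protocols, mice received 1 injection of AOM, a DNA-alkylating carcinogen, at 10 mg/kg. After 7 days they drank water with 2% DSS, which injures the colonic epithelium, for 7 days, then plain water for 14 days, with 3 DSS cycles in all. The 0-week arrays came from untreated animals, the 1-week arrays from mice given AOM alone, and the 2-week and 10-week arrays from mice given AOM and DSS. The labels call the 10-week tissue tumour and the 1-week and 2-week tissue colitis, although DSS started only after 1 week. The labels do not say whether each array held RNA of a separate animal, so p-values measure the spread between these arrays, part of which may be technical.

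Per the file headers, the authors extracted spot intensity values with Agilent Feature Extraction 10.7.1.1. The deposited processed signal is an intensity from which Feature Extraction had subtracted background, with spatial and multiplicative detrending and low values replaced by a surrogate. The mean signal and the local background of each spot are deposited as raw intensity values. The authors also deposited 1 table of log2 values per probe; the sources used here do not say how it was normalized. From the values it was taken as quantile normalized, since all columns had the same quantiles (a median of 2.92 in each), and it correlated with the log2 processed signal of the matching array at 0.995 or more. That table was an alternative, not the main source. Its changes at 10 weeks correlated at 0.9995 across probes with those under quantile normalization, so these 2 alternatives are nearly the same scaling.

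Each array held 180870 spots, 4974 of them controls, and 145548 different probes after controls were left out. Spots that the scanner software flagged as non-uniform or as population outliers were dropped, and spots of 1 probe were averaged on the log2 scale. No spot of a tested probe was saturated. Between 33.3% and 44.4% of the probes were well above background per array. Because this is under 50%, each array's log2 processed signal was scaled by subtracting its 75th percentile over the 42363 probes well above background on all 12 arrays; the percentile over all probes was an alternative. Tests covered the 62391 probes well above background on at least 3 arrays. The 3 arrays per group limit the precision.

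For the probes, the gene name, description and coordinate fields repeat the probe ID or are blank in content, and the reference table holds no probe IDs or probe sequences. The files therefore do not pair probes with genes. The gene lists, cell type markers and long non-coding RNA comparison fixed in advance could not be used, nor could the rule of 1 probe per gene, so all counts are of probes. By ID, 51691 probes carried a catalogue prefix and 93857 the prefix of a custom design. Among the custom probes, 15000 with IDs from 75000 to 89999 held more CG than GC dinucleotides and are treated as a separate family.

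Group means were fitted to the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method. A probe was called changed at an adjusted p below 0.05, and the number that also moved by at least 2-fold is given beside it. Contrasts were 1, 2 and 10 weeks against 0 weeks, 2 weeks against 1 week, and 10 weeks against 2 weeks, with a moderated F-test over the 4 time points. Probes moving in the same direction at every step were those past the F-test whose group means rose or fell throughout. The other orders of the 4 means were counted in the same way. This count, the simulations of overlapping lists and the differences between control probes numbered 5 and 3 were chosen after the results were seen. For those simulations the called changes were shuffled over probes of similar variance, separately for each comparison, and noise was added to 12 arrays. On data simulated with 200 changed probes among 62391, 24.0% to 37.0% of 2-fold and 68.0% to 76.0% of 4-fold changes were recovered, with 5 to 9 false calls. Each comparison had 1 simulated set with the same settings, so these ranges reflect the random draws. The Benjamini-Hochberg threshold depends on how many probes change, so the rates do not describe comparisons with many more changed probes. The rule fixed for named items took the largest rises and falls past the threshold, with groups that did not overlap and at least 2 of 3 arrays well above background in both groups. With no gene names, the rule was applied to probes and not to genes. Only the 2 largest rises and 2 largest falls at 10 weeks are named, by probe ID, a number not fixed in advance. Probes seen in only 1 of the groups are counted, not named.

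Control spots were kept out of all scaling and tests. The control probes that the files name for mouse GAPDH and PGK1 were examined separately, with an exact permutation test of equal means over the 4 groups (scipy 1.17.1), adjusted over the 4 probes. For quantile and cyclic loess scaling, their levels were interpolated from those of the other probes of the same array.

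The alternatives chosen before the data were examined were normexp background correction, quantile normalization, the percentile over all probes, the deposited log2 values, no filter, a filter on all 12 arrays, eBayes with trend and robust options, array weights, only the compared groups, the replicate number as a block, the slide as a random block, and each array left out in turn. Cyclic loess, subsets of probes, and fits without the 10-week arrays or the 3 arrays with the brightest spike-in were added after seeing the data, as were the counts of calls shared by 6 scalings (the main one, the percentile over all probes, quantile, normexp, cyclic loess and the deposited values). Without the deposited values, 4827 probes were higher and 5641 lower at 10 weeks in the other 5, against 4822 and 5638 in all 6. Normexp was run with an offset of 50 added to each signal, which shrinks log2 changes of dim probes. The arrays lay on 6 slides and 2 scan days. All 10-week arrays lay on 1 slide and were alone on their scan day, so scan day and group cannot be told apart there. The 2-week arrays also had a slide of their own. No slide held arrays of more than 1 group, so slide and group cannot be told apart in any comparison. Untreated arrays came only from 0 weeks, so elapsed time and treatment cannot be told apart either. Other versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.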

Results

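The series followed gene expression in mouse colorectal tissue from the untreated state at 0 weeks, through 1 week after the carcinogen AOM and 2 weeks after AOM with the first DSS course, to tumour tissue at 10 weeks. Each time point had 3 arrays. Between 48439 and 64592 probes per array were well above background, and the 10-week arrays had the most, at 59308 to 64592. Arrays of 1 group correlated with each other at 0.970 to 0.978 across 62363 probes, and arrays of different groups at 0.908 to 0.972; probes are not independent replicates. The first principal component, with 41.1% of the variance, set the 10-week arrays apart from all others. The second, with 17.1%, placed the 0-week arrays at scores of -85.8 to -52.4, the 1-week arrays at -23.3 to 30.1 and the 2-week arrays at 52.2 to 98.7, while the 10-week arrays, at -21.2 to 3.51, lay among the 1-week arrays.

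**Figure D1:**
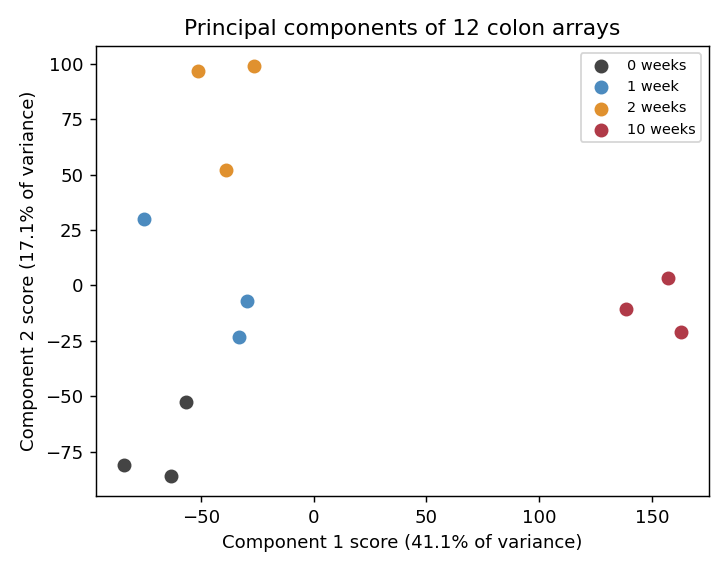
Scores of the 12 arrays on the first 2 principal components of the scaled log2 levels (arbitrary units), 1 point per array, coloured by week. The 10-week arrays have component 1 scores of 138 to 163, and no other array exceeds -26.2.

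The most probes changed at 10 weeks. Against 0 weeks, 20699 of 62391 tested probes changed (33.2%), 10797 of them by at least 2-fold (limma, Benjamini-Hochberg adjusted p). Of the changed probes, 10460 were called in the same direction under all 6 scalings, 4822 higher and 5638 lower. Adding the fits that left out each array in turn kept 8436 of these, 4707 higher and 3729 lower. Those fits used the main scaling only, and 7945 probes were higher and 3799 lower in all of them. The turn in balance therefore does not show that falls depended more on single arrays.

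The balance of rises and falls at 10 weeks depended on the scaling. The main scaling gave 14226 probes higher and 6473 lower, with a median change over all tested probes of 0.23 on the log2 scale. The percentile over all probes gave 6795 higher and 13363 lower, with a median of -0.12. The split was 8691 higher and 9620 lower with quantile normalization, 8653 and 8476 with cyclic loess, 10174 and 8303 with normexp, and 8645 and 9567 in the deposited log2 values. The 10-week arrays shared 1 slide and scan day with no other group, so these technical differences and the tumour state cannot be told apart. Untreated arrays came only from 0 weeks, so the time elapsed cannot be told apart from them either.

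**Figure D2:**
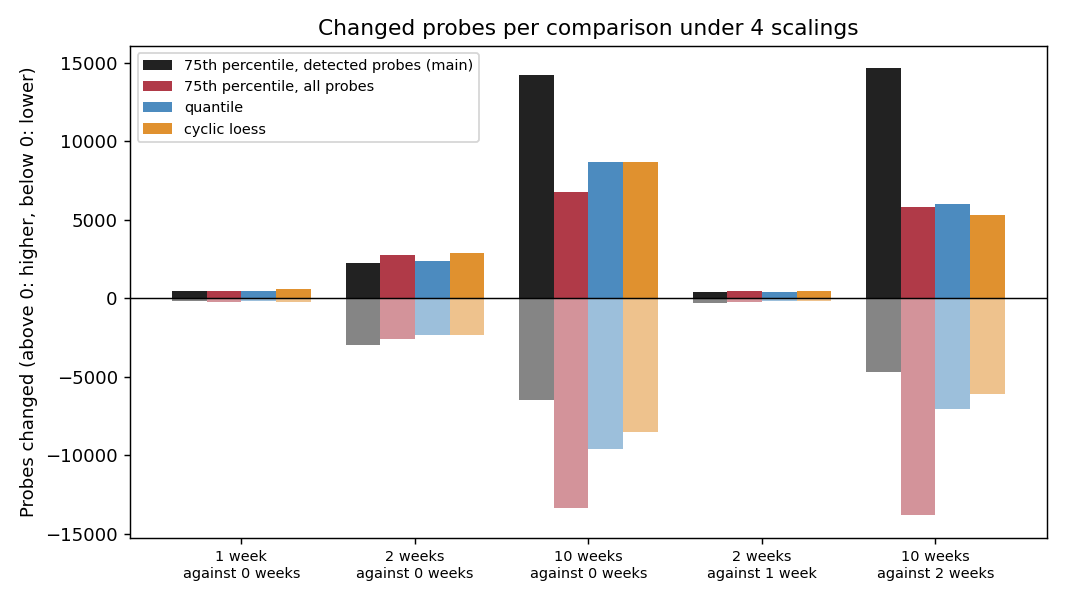
Number of probes changed in each comparison, higher above 0 and lower below 0 (paler bars), under 4 scalings. At 10 weeks against 0 weeks the larger side turns from 14226 higher with the main scaling to 13363 lower with the percentile over all probes.

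By the threshold, overlap and background criteria fixed in advance, but applied per probe and not per gene, the 2 largest rises at 10 weeks were probes A_55_P2104071 and A_55_P1999108. Probe A_55_P2104071 (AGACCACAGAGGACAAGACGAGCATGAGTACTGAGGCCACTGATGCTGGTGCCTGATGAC) averaged -4.85 ± 0.41 (SD, n = 3) at 0 weeks and 4.23 ± 0.99 at 10 weeks on the log2 scale. This was a rise of 9.09 (SE 0.40), with a limma adjusted p of 8.1e-07, and of 6.76 with normexp; 1 of the 3 arrays at 0 weeks was not well above background. Probe A_55_P1999108 (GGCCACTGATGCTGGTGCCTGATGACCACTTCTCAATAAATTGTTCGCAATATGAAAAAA) rose by 8.49 (SE 0.45) from -4.68 ± 0.47 to 3.82 ± 0.94 (SD, n = 3; limma adjusted p = 1.35e-06). With normexp this rise was 6.30. The normexp setting added an offset of 50 to each signal, which by itself shrinks rises that start from dim signals. The smaller values therefore do not show that the background estimate matters. The probes share a stretch of 26 bases, so they are not independent measurements. Neither passed the threshold at 1 or 2 weeks, and each was well above background on at most 1 of the 3 arrays there.

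The 2 largest falls at 10 weeks were probes A_55_P2092633 and A_55_P2057189, and both had already fallen at 2 weeks. Probe A_55_P2092633 (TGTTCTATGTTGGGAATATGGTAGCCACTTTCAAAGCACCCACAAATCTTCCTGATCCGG) averaged 7.47 ± 0.20 (SD, n = 3) at 0 weeks and 7.61 ± 0.28 at 1 week. It averaged -0.25 ± 2.09 at 2 weeks and -0.05 ± 0.44 at 10 weeks. Its log2 change against 0 weeks was -7.72 at 2 weeks (limma adjusted p = 0.000324) and -7.51 (SE 0.76) at 10 weeks (limma adjusted p = 0.000103). Probe A_55_P2057189 (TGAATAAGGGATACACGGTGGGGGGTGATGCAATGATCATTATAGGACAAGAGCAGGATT) had changes of -7.18 at 2 weeks (limma adjusted p = 0.000176) and -7.01 (SE 0.64) at 10 weeks (limma adjusted p = 5.46e-05). The genes behind these 4 probes are not paired with them in the files.

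**Figure D3:**
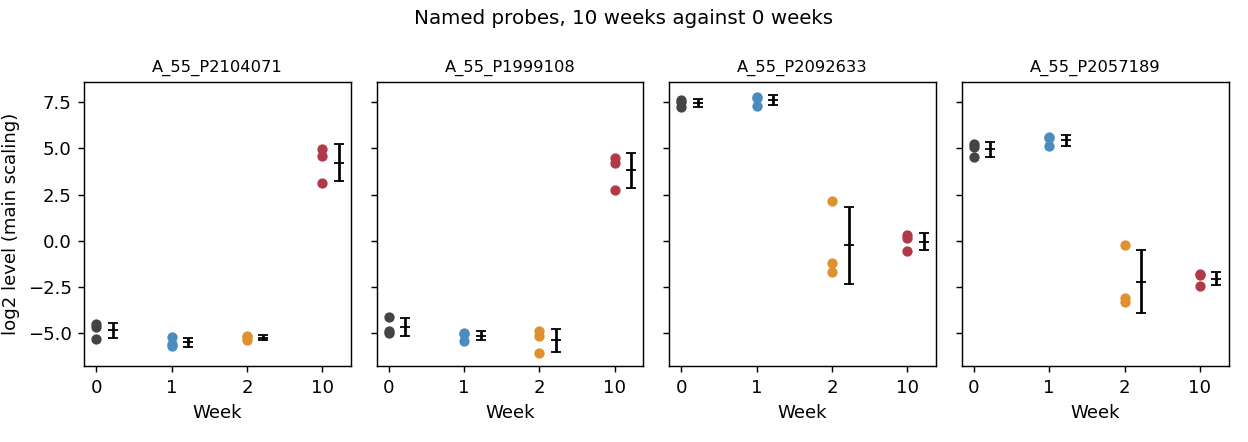
Scaled log2 level of the 4 named probes by week, 1 point per array, with the group mean and SD (n = 3) beside the points. The rising probes are near -5 until 2 weeks and near 4 at 10 weeks, while the falling probes drop between 1 and 2 weeks, from 7.61 to -0.25 for A_55_P2092633.

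At 2 weeks against 0 weeks, the comparison that spans the first DSS course, 5216 probes changed, 2250 higher and 2966 lower, and 3072 of them by at least 2-fold. Under all 6 scalings, 1606 were higher and 1085 lower. The split was 2899 higher and 2285 lower with normexp and 2892 and 2338 with cyclic loess. Among catalogue probes 1735 were higher and 1412 lower, and among custom probes 446 were higher and 1511 lower. Custom probes of inverted composition had 69 higher and 43 lower. Counts fell to between 1790 and 2186 without 0-week replicate 1, 0-week replicate 2, 2-week replicate 1 or 2-week replicate 3, and 1050 probes were called in all scalings and all fits that left out an array.

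Of the 5216 probes changed at 2 weeks, 2645 (50.7%) had changed in the same direction at 10 weeks and 158 in the opposite direction, each against 0 weeks. Independent lists would share 821 in the same direction. In 20 simulations with changes placed on probes independently and the same controls, lists of 4175 and 17672 probes shared 627 on average, where independent lists of these sizes would share 566. Of the probes changed at 2 weeks, 2047 moved back between 2 and 10 weeks, 417 that had risen and 1630 that had fallen, and 475 moved further. The same 2-week arrays served to choose and to score these probes, which favours a move back. With calls shared by all 6 scalings, 795 probes were higher and 490 lower at both times (124 and 98.0 for independent lists), and 22 were opposite. Of these shared calls at 2 weeks, 487 moved back, 322 that had risen and 165 that had fallen. Both comparisons used the same 0-week arrays, and part of the overlap may come from these. Across probes, the changes at 2 and 10 weeks against 0 weeks correlated at r = 0.499, where unchanged groups simulated against the same controls gave 0.497. The covariance was 0.283, against 0.0476 in the simulation.

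Without shared arrays, the change from 1 to 2 weeks and the change from 0 to 10 weeks correlated at r = 0.196 across 62391 probes (Spearman's rho = 0.0875), and the simulated value was -0.00410. Among the brightest 20797 probes r was 0.381, and with no filter 0.0768. Of 697 probes changed between 1 and 2 weeks, 358 changed in the same direction at 10 weeks against 0 weeks, where independent lists would share 124, and 90 changed in the opposite direction. With calls shared by all 6 scalings, 137 were higher and 38 lower in both, and 24 were opposite.

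Between 1 and 2 weeks, the step in which DSS was given, 419 probes rose and 278 fell, and 596 of these 697 moved by at least 2-fold. Normexp gave 465 higher and 170 lower. Without 2-week replicate 2 the balance turned, with 351 higher and 601 lower. Under all 6 scalings 289 were higher and 65 lower, and 330 of these 354 were on catalogue probes. Counts were 330 without 2-week replicate 3, 346 without 1-week replicate 3, 389 without 1-week replicate 1 and 437 without 2-week replicate 1.

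At 1 week, after AOM and before DSS, 610 probes differed from 0 weeks, 440 higher and 170 lower, and 487 by at least 2-fold. Under all 6 scalings 235 were higher and 71 lower. Of the 610 probes, 442 also changed in the same direction at 2 weeks, where independent lists would share 23.9. In the same simulations lists of 470 and 4175 probes shared 23.3 on average, where independent lists would share 14.9. Both comparisons used the same 0-week arrays, and part of the overlap may come from these. Normexp gave 851 higher and 534 lower. The largest rise that met the rule was 5.59 on the log2 scale, or 48.3-fold (SE 0.61, limma adjusted p = 0.00666), and 3.77 with normexp. This probe did not pass the threshold when only the 2 groups were fitted (limma adjusted p = 0.0501) or without the 3 arrays with the brightest spike-in (limma adjusted p = 0.177). The second largest rise by the rule was 5.11 (SE 0.39, limma adjusted p = 0.0004), and it passed under all 28 other settings. The 2 largest falls by the rule, -3.99 and -2.73, did not pass under 9 of 27 and 8 of 28 other settings. The number of changed probes depended on single arrays, from 46 without 0-week replicate 1 to 1148 without 0-week replicate 3. Only 35 probes were called in every fit that left out an array, and 13 when only the 2 groups were fitted.

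Between 2 and 10 weeks 19356 probes changed, 14642 higher and 4714 lower, with 10021 by at least 2-fold and a median change over all tested probes of 0.27. With the percentile over all probes the split was 5784 higher and 13816 lower, with a median of -0.14. It was 6005 and 7022 with quantile normalization, 5301 and 6116 with cyclic loess, 7173 and 6224 with normexp, and 5934 and 6974 in the deposited log2 values. Calls shared by all 6 scalings were 2797 higher and 3463 lower. The count was 11258 without 2-week replicate 3 and 12021 without 10-week replicate 1.

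Across the 4 time points 23165 probes changed by the F-test, and 14920 without 10-week replicate 1. Of the 23165 probes, 5164 (22.3%) moved in the same direction at every step, 2976 rising and 2188 falling. If all orders of the 4 means were equally frequent, 8.33% would. The single steps did not have to pass a threshold. Only 367 probes were called in the same direction at 1, 2 and 10 weeks, each against 0 weeks. Most probes past the F-test had their 10-week mean at 1 end, and of these 26.2% followed the order of the weeks. With 10 weeks at 1 end, the next most frequent order of the means, with 0 weeks beside 10 weeks and 2 weeks at the other end, held 3936 probes (20.0%), and the rarest 2077. The percentile over all probes gave 1352 rising and 3230 falling, quantile normalization 2114 and 2904, normexp 2606 and 2608, cyclic loess 2191 and 2572, and the deposited values 2099 and 2895. Under all 6 scalings, 773 rose and 1504 fell at every step.

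Some probes were well above background on all arrays of 1 group and on none of another. At 10 weeks, 2926 probes were seen on all 3 arrays and on none at 0 weeks, and 473 the other way. At 2 weeks 351 were seen that way and 1220 the other way, and at 1 week 389 and 281. The highest total in the other splits of the same 6 arrays was 267 at 10 weeks, 247 at 2 weeks and 399 at 1 week. Detection was called on each array before scaling. The median signal over all probes was 10.0 to 11.1 on the 10-week arrays and 5.92 to 6.56 on the 0-week arrays. The other splits cannot separate such a difference between arrays, or slide and scan day, from the group.

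The only probes named for mouse genes were control probes for GAPDH, a glycolytic enzyme, and PGK1, another enzyme of glycolysis. Probe PGK1_5 averaged 1.58 ± 0.12 (SD, n = 3) at 0 weeks, 2.05 ± 0.15 at 1 week, 2.43 ± 0.32 at 2 weeks and 1.95 ± 0.13 at 10 weeks on the log2 scale. The groups differed (exact permutation test, adjusted p = 0.00156 over 4 probes), and all 3 arrays at 1 week and at 2 weeks lay above every 0-week array. PGK1_3 was higher by 0.48 and GAPDH_5 by 0.46 at 2 weeks, each on 3 of 3 arrays (exact permutation test over the 4 groups, adjusted p = 0.0156 for both). GAPDH_5 was among the brightest control probes, with an unscaled signal of 53350 at 0 weeks and 70250 at 2 weeks. Saturation was not counted for control spots, so a ceiling on this probe is not excluded. The level of the probe numbered 5 minus that of the probe numbered 3 was compared on the same array; the files do not say what these numbers mean. This difference exceeded that at 0 weeks by 0.30 for GAPDH and 0.36 for PGK1 at 2 weeks and by 0.59 and 0.35 at 10 weeks, and lay above every 0-week array on 3 of 3 arrays at each later time (exact permutation test over the 4 groups, unadjusted p = 0.0559 and 0.0415), so GAPDH did not pass the threshold. Against 0 weeks, the same difference at 2 and 10 weeks was 0.54 and 0.56 for the human PGK1 pair, 0.79 and 0.37 for rat PGK1, 0.44 and -0.06 for rat GAPDH, and -0.34 and -0.37 for human GAPDH. Rat PGK1_3 had an unscaled 0-week signal of 2.99, between those of 2 kinds of negative control spot (2.66 and 3.31). It was not above background there, so the rat PGK1 difference mainly follows the probe numbered 5. The 2-week change of mouse PGK1_5, PGK1_3 and GAPDH_5 against 0 weeks had the same sign under all 6 scalings. The adjusted p of PGK1_3 in the exact permutation test reached 0.0570 with cyclic loess and 0.0552 in the deposited values. At 10 weeks PGK1_3 was higher by 0.02 with the main scaling and lower, at -0.32, with the percentile over all probes, and GAPDH_5 turned from 0.18 to -0.16. PGK1_5 went from 0.37 to 0.02, with 1 array below every 0-week array under the latter scaling. GAPDH_3 did not pass the test (exact permutation test, adjusted p = 0.103) and passed with the percentile over all probes (adjusted p = 0.0291).

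**Figure D4:**
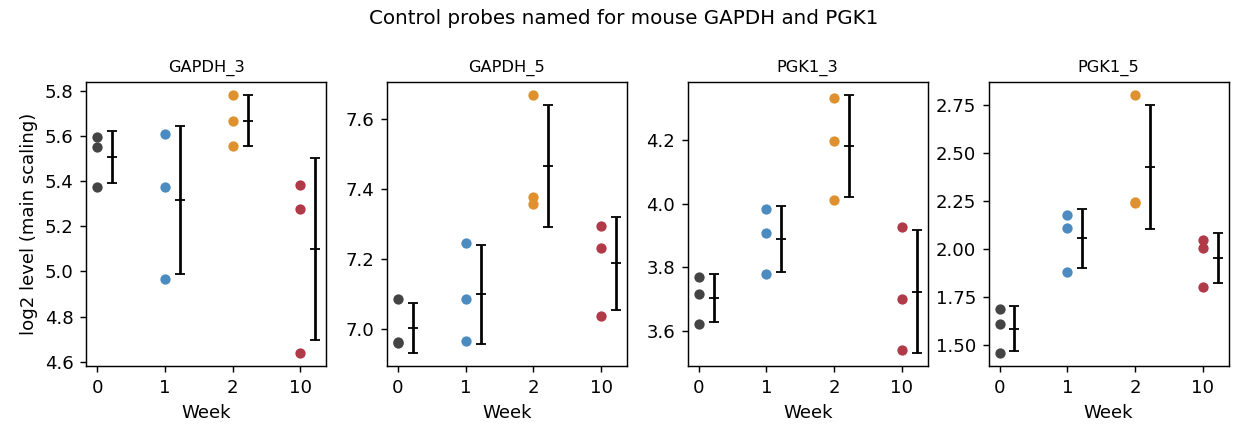
Scaled log2 level of the 4 control probes named for mouse GAPDH and PGK1 by week, 1 point per array, with the group mean and SD (n = 3) beside the points; the vertical scales differ between panels. PGK1_5 averages 1.58 at 0 weeks and 2.43 at 2 weeks.

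The direction of change at 10 weeks went with signal level under the main scaling. Of the brightest 20797 tested probes 3009 were higher and 3742 lower; of the dimmest 20797, 5937 were higher and 966 lower. A probe could be tested on the strength of the 10-week arrays alone, which favours dim probes that rose. Ordered by the 1- and 2-week arrays, the median change of the dimmest 10% minus that of the brightest 10% was 1.01 among the tested probes. It was 0.62 among probes also chosen by those arrays, and 0.50 among probes well above background on all 12 arrays. With no filter it was 0.14, but most probes were then not well above background. Catalogue probes had 6757 higher and 5060 lower, custom probes 6492 and 1346, and custom probes of inverted composition 977 and 67. With calls shared by all 6 scalings, catalogue probes had 2458 higher and 4422 lower, and custom probes 2049 and 1159.

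**Figure D5:**
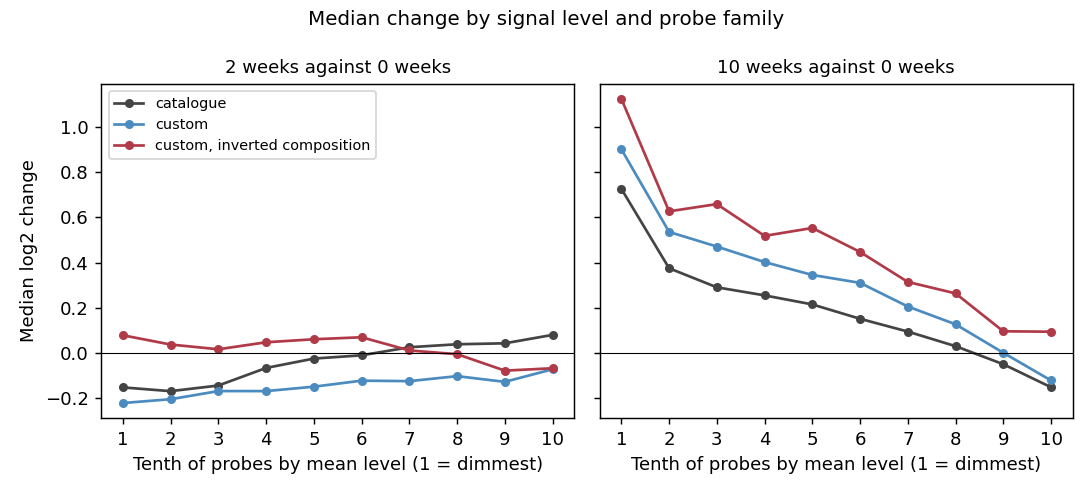
Median log2 change (main scaling) in 10 equal bins of the tested probes ordered by mean level over all 12 arrays (1 is dimmest), for the 3 probe families, at 2 and 10 weeks against 0 weeks. At 10 weeks the catalogue median goes from 0.73 in the dimmest bin to -0.15 in the brightest; the 10-week arrays took part in choosing the probes, which favours dim probes that rose.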

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

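All tests in this part were chosen after the results were seen, except the counts over other splits and the test of GC content. Under the main scaling, 23 probes were higher at 2 weeks and lower at 10 weeks against 0 weeks and 135 the other way, each with the difference between 2 and 10 weeks past the threshold of limma. Under all 6 scalings these numbers were 13 and 9. Among the 68 control probes, which the comparisons did not use, the spike-in control ERCC-00012_90 was higher by 1.30 on the log2 scale of the unscaled signal at 10 weeks, with every 10-week array at least 1 above every 0-week array. Its 0-week signal lay between those of 2 kinds of negative control spot, so it was not above background there. All 3 arrays lay above all 0-week arrays on the same unscaled signal for 37 control probes at 10 weeks, 10 at 2 weeks and 6 at 1 week, where 3.4 would by chance; the 68 include the GAPDH and PGK1 probes. This signal keeps differences in brightness between arrays. The 75th percentile of probes well above background on all arrays was 463 to 528 at 10 weeks and 409 to 425 at 0 weeks. The negative control (-)3xSLv1 was higher by 0.24 at 10 weeks. The control probes are therefore not independent, and 1 shared offset may underlie part of the 37. The negative control went only from 2.66 to 3.14, and an offset of that size does not give the larger rises. These included ETG05_66023 (61.4 to 130), DCP_20_5 (18.2 to 35.8) and ERCC-00062_278 (25.2 to 44.8), each with every 10-week array above every 0-week array. Other controls did not separate in this way, such as DCP_20_1 (31.5 to 33.2) and E1A_r60_1 (-0.09 on the log2 scale). The cause was not tested.

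At 10 weeks more probes were higher than lower, and dim probes rose against bright ones. The excess of rises was not kept with another scaling factor per array: only 33.7% of changed probes were higher with the percentile over all probes. Another factor moves all probes of an array alike, so this turn does not show whether 1 unsuitable factor per array made the excess. Such a factor would leave no trend with level, but among the 53354 probes well above background on at least 3 of the 1- and 2-week arrays, chosen and ordered without either compared group, the dimmest 5336 changed by 0.62 more than the brightest 5336 (0.52 to 0.75 on the 3 arrays; 0.14 with no filter). A candidate explanation is signal that is not specific to each probe's transcript. In this set custom probes of inverted composition rose by 0.28 more than catalogue probes of the same level (0.22 to 0.42). Among probes well above background on all 12 arrays this gap was 0.24 (0.16 to 0.41), and the trend with level was 0.50 (0.43 to 0.60). With no filter the gap was 0.03. Most probes were then not well above background, so the values with no filter say little about detected probes. Among all tested probes, other custom probes also had higher medians than catalogue probes of similar level. The dimmest bin had 0.73 for catalogue, 0.90 for other custom and 1.12 for inverted probes, and the brightest -0.15, -0.12 and 0.09. GC content, on average 42.2% for catalogue and 45.7% for inverted probes, was not matched. The gap therefore does not single out this explanation, which stays open. Slide and scan day stay open because 0 arrays of other groups shared them. The tumour state and the time elapsed since 0 weeks also stay open, since no test here separates them from slide and scan day.

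At 2 weeks custom probes had more falls than rises, while catalogue probes had more rises. Custom probes of inverted composition, kept apart here, also had more rises (69 higher and 43 lower). The median change of custom minus catalogue probes was -0.15 (-0.25 to -0.08 on the 3 arrays). Among probes of the same GC content it was -0.16, which argues against GC content. Among probes of the same level it was -0.0941, but -0.0466 on 1 array, so the lower level of the custom probes may account for part and stays open. The slide cannot be told apart from the treatment, since 0 arrays of other groups lay on it, and a difference between the transcripts of each family after DSS was not tested.

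In 100 splits of the 12 arrays into 4 groups, the real one included, only 1 gave as many probes as the F-test count of 23165, and the highest other count was 6485. The arrays therefore differed by group more than under random splits. No slide held arrays of more than 1 group, and arrays may not be separate animals, so differences between slides or animals are not excluded. Likewise 1 of 100 gave as many as the 5164 probes moving in the same direction at every step, with 55 as the highest other. The other splits also lost the probes past the F-test, so this count speaks to differences between the groups and not to the order of the weeks. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, reached the real count each time, and the highest other count was lower: 610 against 253 at 1 week, 5216 against 0 at 2 weeks, 20699 against 1 at 10 weeks, 697 against 1 between 1 and 2 weeks, and 19356 against 1 between 2 and 10 weeks.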

How the results depend on the processing

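Cyclic loess, the brightest 20797 probes, and the fits without the custom probes of inverted composition, the 3 arrays with the brightest spike-in or the 10-week arrays were chosen after seeing the data; for the values listed, the cause was not tested unless fewer probes or arrays are named. At 10 weeks against 0 weeks the count stayed within 1.5 times of 20699 under 13 of 15 other settings and without any 1 array (14470 to 21508), although the balance of directions turned with the scaling. At 1 week against 0 weeks 610 became 1385 with normexp, 173 with no filter, 1024 with the filter on all 12 arrays, 1337 with trend and robust eBayes and 1389 with the slide as a random block, whose correlation was -0.0892. It became 13 with only the 2 groups, which leaves fewer arrays to estimate the spread, 184 without the 10-week arrays and 15 without the 3 bright spike-in arrays. At 2 weeks against 0 weeks 5216 became 2517 with no filter, 8853 with array weights, 3295 with only the 2 groups, 8757 with the slide block, 2795 among the brightest 20797 probes and 1333 without the 3 arrays. Between 1 and 2 weeks 697 became 388 with no filter, 291 with only the 2 groups, 1286 with the slide block, 320 among the brightest probes and 201 without the 3 arrays. With cyclic loess, 11417 probes changed between 2 and 10 weeks. Among the brightest 20797 probes, where fewer were tested, 8276 changed at 10 weeks against 0 weeks, 6111 between 2 and 10 weeks and 9246 over the 4 time points, and 2673 moved in the same direction at every step. Without the 3 arrays, where fewer arrays were fitted, these counts were 9077, 10288, 7900 and 1892. The correlation of the 2-against-1-week and 10-against-0-week changes, 0.196, was 0.314 with normexp, 0.0768 with no filter, 0.245 with the filter on all 12 arrays or cyclic loess, 0.381 among the brightest probes and 0.252 without the 3 arrays.

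Leaving out each array in turn gave 46 to 1148 probes at 1 week against 0 weeks. The count was 46 without 0-week replicate 1, 55 without 1-week replicate 3, 114 without 0-week replicate 2, 123 without 1-week replicate 2, 336 without 10-week replicate 3, 367 without 10-week replicate 2, 385 without 2-week replicate 3 and 1148 without 0-week replicate 3. At 2 weeks against 0 weeks the range was 1790 to 5815, with 1790 without 0-week replicate 1, 1879 without 2-week replicate 3, 1986 without 0-week replicate 2 and 2186 without 2-week replicate 1. Between 1 and 2 weeks it was 330 to 952, the latter without 2-week replicate 2, where 351 were higher and 601 lower, and the counts that moved by over 1.5 times were 330 and 437 without 2-week replicates 3 and 1 and 346 and 389 without 1-week replicates 3 and 1. Between 2 and 10 weeks it was 11258 (without 2-week replicate 3) to 20350, with 12021 without 10-week replicate 1. Over the 4 time points it was 14920 (without 10-week replicate 1) to 23351, at every step 3554 to 5092, and for the correlation 0.132 to 0.230. The 4 named probes stayed past the threshold in the same direction under every setting that tested them.

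The replicate numbers did not pair the arrays: deviations from the group means of same-numbered arrays correlated at -0.0988 to 0.191, and 4 of 12 arrays correlated best with their own number. With the replicate number as a block, 316 probes changed at 1 week against 0 weeks, and no other count moved by more than 1.5 times. The scan date as a block, the mean over probes of a gene, the gene lists and the long non-coding comparison were not run, the first because the 10-week arrays alone had the second day and the others because the files do not pair probes with genes. Signal over background limits what can be seen: at most 44.4% of probes were well above background on an array.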

Other observations

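The tests in this part were chosen after the results were seen. The 15000 custom probes with IDs from 75000 to 89999 averaged 2.81 CG and 1.03 GC dinucleotides per probe, where the other custom probes averaged 0.557 and 2.43. Only 20.5% were well above background on at least 3 arrays, against 33.2% of the other custom probes and 64.2% of the catalogue probes. A hypothesis is that their sequences were reversed end to end. Read backwards, they shared 40 or more bases with a catalogue probe in 96 pairs, while the other custom probes did so in 0 pairs and matched in the same direction in 135. In 2 further pairs the block matched in the same direction, so a reversal was not shown for all of it. In the reversed pairs 13.5% of the custom probes and 86.5% of their catalogue partners were detected, a difference of -72.9 percentage points; in the 135 pairs of the same direction the values were 58.5% and 52.6%. This is consistent with probes reversed on the array itself, and it argues against a reversal in the file alone, since such probes would be detected like their partners. Without these probes 19783 probes changed at 10 weeks against 0 weeks.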
